A study of Mus musculus with 6 samples.

How the data were processed

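Total RNA from cultured mouse B-cell progenitors was prepared with TRI reagent, and 100 ng per sample was converted to biotin-labelled sense-strand cDNA with the Affymetrix WT Plus assay, per the labels' protocols. Each of the 6 samples was hybridised to an Affymetrix Mouse Gene 2.0 ST array, a 1-colour array with many probes per transcript. The deposited values are log2 expression, 1 value per transcript cluster and array, summarised and normalized by RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA subtracts background, makes the distributions of the arrays nearly alike and combines the probes of a transcript, which compresses differences among dim genes and removes shifts shared by all genes. The version and settings are not given in the sources used here. The log2 scale was read from the deposited values, which lay between 1.82 and 13.8.

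The table held 41345 probes, here meaning transcript clusters. The platform annotation used names 1 gene symbol for 23521 of them and several for 1820. It lists no gene for 16004, which are unnamed here and not without a gene. Symbols were updated through Entrez gene identifiers with a RefSeq gene table of assembly GRCm38.p6. That table held the identifiers of 23328 single-gene probes and not those of 193, which kept their older symbols. The array's genome build is not given in the sources used here, so no coordinates are printed. Probes with exactly 1 symbol entered the tests. For the 1082 genes with more than 1 probe, the probe with the highest mean over all 6 arrays was used, without regard to group, which left 22180 genes. No filter on dim genes was applied. The list of mitochondrially encoded genes had 0 measured members and was not tested.

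Groups were taken from the titles, which the source names repeat, with 3 arrays per group. The genotype field gives the opposite grouping. Differences are KRASG12D-titled minus vector-titled. They were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the single factor, 4 residual degrees of freedom), with Benjamini-Hochberg adjustment over all genes and a threshold of adjusted p below 0.05. A gene called higher or lower, risen or fallen passed that threshold. A ± after a level is the SD over 3 arrays, and a ± after a log2 difference is its standard error. Folds are 2 raised to the log2 difference.

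Before the data were examined, 40 gene lists, the tests, the alternatives and the rule for named genes were fixed. Each list with at least 5 measured members, 36 in all, was tested with camera. This limma test asks whether a list's genes shift up or down together relative to other genes. A list whose genes go both ways can therefore have a large camera p. A preset correlation between genes of 0.01 was used, with Benjamini-Hochberg adjustment over the lists. The alternative estimates the correlation for each list, and fry was run beside it. Unlike camera, fry does not compare a list with other genes, so most lists can pass it when many genes differ. Some genes stand in more than 1 list. The rule named the 12 largest positive and 12 largest negative differences among called genes whose groups do not overlap. It left out predicted gene models, immunoglobulin and T-cell receptor segments, microRNAs, small nucleolar RNAs and olfactory or vomeronasal receptors. It added up to 4 called members of each list with the largest differences, and a fixed set of genes whatever their result. The fixed set held Kras, Dusp6, Spry2, Etv5, Myc, Ccnd1, Cdkn2a, Rag1, Rag2, Dntt, Vpreb1, Igll1, Il7r, Ebf1, Pax5, Ikzf1, Xist and the Y-linked genes. Of these, Kras, Rag1 and Ddx3y had no probe named for them alone and were not analysed here. The rule gave 161 genes with values. For 13 of them more than 1 probe was named, and for 0 of these did another probe pass limma's test in the opposite direction. Genes outside the rule are said to be chosen after their values were seen.

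The fit was tested on simulated arrays with the means and spread of the real ones, in which 200 of 22180 genes were changed. It recovered 52.2%, 88.1% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale in the simulated comparison of titled groups. There were 13 false calls (7.51% of calls). In the real data 24.9% of genes passed, and the adjustment depends on that share. These rates therefore hold only for the simulated setting. The alternatives were the title's replicate number as a block, leaving out each array in turn, quantile normalization, median centring, a filter on the dim 40% of genes, and the mean of all probes of a gene. Further alternatives were every probe in the table, eBayes with trend and robust settings, array weights (statmod 1.5.0) and the genotype field. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.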

Results

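Gene expression was measured in cultured mouse B-cell progenitors, the bone-marrow stages that precede the mature B cell. The cells carried either an empty vector or KRASG12D, an activated form of the small GTPase KRAS. The design asks how transformation by KRASG12D changes the transcriptome of these progenitors. There were 6 arrays, 3 titled as vector and 3 titled as KRASG12D. All cells were grown in the same medium with 20% serum and 10 ng/ml of interleukin 7 (IL-7), the cytokine on which such progenitors grow. The array median over all probes lay between 5.22 and 5.27 on the log2 scale, and 22180 genes were tested. The number of arrays limits the precision. The labels do not say whether the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

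The submitters' labels contradict each other. The titles and source names give 1 grouping, and the genotype field gives the opposite grouping for all 6 arrays. Groups were set by the title, and every direction below is that of the KRASG12D-titled arrays relative to the vector-titled arrays. Grouping by the genotype field would turn every sign and leave every size as it is. No probe was named for Kras alone in the annotation used, so the introduced gene itself could not check the labels.

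Genes that RAS signalling through the kinase ERK is known to induce were therefore examined first, and 16 of 28 were higher in the KRASG12D-titled arrays. Dusp6, the phosphatase that switches off ERK, stood at 10.32 ± 0.02 against 7.67 ± 0.04 (log2 mean ± SD, n = 3 each), a 6.27-fold difference (probe 17236882). Etv5, an ETS transcription factor downstream of ERK, was 9.22-fold higher, with a log2 difference of 3.20 ± 0.10 (SE). A second, dimmer probe for each of these genes gave a difference of 0.66 for Dusp6 and 0.37 for Etv5. The urokinase receptor gene Plaur was higher by 2.73 ± 0.17, and Spred2, another brake on the pathway, by 2.48 ± 0.06. Ccnd1, which encodes cyclin D1, was higher by 1.28 ± 0.10, and the feedback inhibitor Spry2 by 0.74 ± 0.10. Of these 28 ERK feedback and output genes, 2 were lower and 10 did not pass the threshold. The counts were 16 and 5 when adjusted over the list alone. The genes that went down, named after their values were seen, were Epha2, a receptor tyrosine kinase, with a difference of -0.87, and Fosb at -0.36. Myc, at 11.30 ± 0.01 and 11.33 ± 0.02, did not pass the threshold (adjusted p = 0.791, limma). The list's median log2 difference was 0.52, and limma's camera test gave an adjusted p of 6.35e-06, against adjusted p = 0.124 with an estimated correlation. The list's direction in this test matches the titles and not the genotype field. Myeloid-associated markers, described further on, rose in the same arrays (12 of 29). Only these groups were compared, so all differences lie in the same arrays by design. This and later mentions of it show no link between gene lists. They only recall that other cells may contribute.

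The titled groups were far apart. Arrays of the same group correlated at 0.995 to 0.996 across genes, and arrays of different groups at 0.964 to 0.967, where genes are not independent replicates. The first principal component held 84.7% of the variance and separated the groups, and the second held 4.83%. In the limma fit 5512 genes (24.9% of those tested) passed an adjusted p of 0.05, 2917 of them higher and 2595 lower in the KRASG12D-titled arrays. At least a 2-fold difference was found for 1097 genes, 611 higher and 486 lower. The 2-fold count was 1689 over every probe in the table, named or not. A difference of 8-fold or more was found for 133 genes, 85 higher and 48 lower. The groups did not overlap for 8691 genes (39.2%), where chance gives 10% with 3 against 3. The median standard error of a log2 difference was 0.0897.

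**Figure D1:**
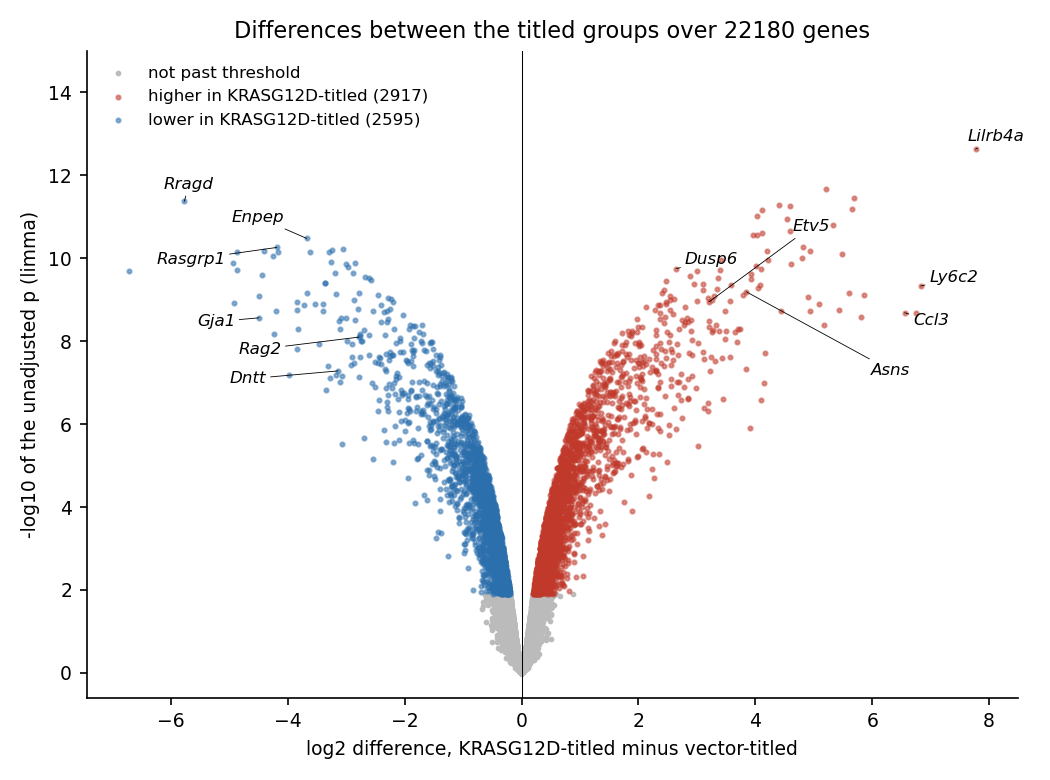
Each point is 1 of 22180 genes, placed by its log2 difference (KRASG12D-titled minus vector-titled) on the horizontal axis and by -log10 of limma's unadjusted p on the vertical axis. The 2917 genes past the threshold and higher in the KRASG12D-titled arrays are red, the 2595 lower ones are blue, and Lilrb4a and Rragd stand at the outer edges among the labelled genes.

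The 12 genes that the naming rule took as largest on the higher side included surface receptors, chemokines and genes best known from myeloid cells. Lilrb4a, an inhibitory immunoglobulin-like receptor, rose from 3.58 ± 0.08 to 11.35 ± 0.10, a 218-fold difference (probe 17233226; adjusted p = 5.25e-09, limma). Ly6c2, a GPI-anchored antigen of monocytes, was 114-fold higher with a log2 difference of 6.83 ± 0.19. Both have near-identical neighbours in the genome, so part of their signal can come from a related gene. The chemokine genes Ccl3 and Ccl9 were higher by 6.55 ± 0.22 and 5.60 ± 0.16. Ly86, which encodes the MD-1 protein, was higher by 5.86, and Cybb, the catalytic subunit of the phagocyte NADPH oxidase, by 5.81. Gapt, an adaptor that binds GRB2, was higher by 5.70, Emb (embigin) by 5.66, Aldh8a1 by 5.49 and Rnase12 by 5.44. Mt2, a metallothionein, was higher by 5.32 and Gria3, a glutamate receptor subunit, by 5.21. A second probe for Emb gave a difference of only 0.10. Except for Ccl9 and Mt2, the vector-titled levels of these genes were below the array medians, where array values are compressed, so their folds and their order rest on dim values on that side.

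On the lower side the largest difference by the same rule was that of Rragd. Rragd, a GTPase through which amino acids activate mTORC1, fell from 10.05 ± 0.05 to 4.28 ± 0.14 (probe 17412539; adjusted p = 1.87e-08, limma). The zinc-finger genes Zfp709 and Zfp760 fell by 4.94 and 4.21 on the log2 scale, and a second Zfp709 probe gave -3.49. Sytl2, a regulator of vesicle traffic, and Slc30a4, a zinc transporter, each fell by 4.86. The gap-junction gene Gja1 (connexin 43) fell by 4.49 ± 0.15. Bmpr2, a receptor for bone morphogenetic proteins, differed by -4.48 and Tgfb3, a growth factor gene, by -4.45. Tspan6, Nt5dc2 and Efhd1 differed by -4.40, -4.25 and -4.24, although a second Efhd1 probe gave -0.22. Rasgrp1, an exchange factor that loads RAS with GTP, fell by 4.18 ± 0.09. Except for Bmpr2 and Nt5dc2, the KRASG12D-titled levels of these genes were below the array medians, so the sizes of their falls and their order rest on dim values.

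The core list of the pathway had 11 measured genes, of the RAS, RAF and MEK families with Ksr1, Ksr2 and Rps6ka3. The ERK genes Mapk1 and Mapk3, and Kras, Hras and Raf1, were not among them. Of the 11, 1 was higher (Map2k1, which encodes MEK1, 0.58 ± 0.10) and 1 was lower (Rras2, -0.47 ± 0.09), also when adjusted over the list alone. The camera test gave an adjusted p of 0.542 for these core genes. Among 16 RAS exchange factors and GTPase-activating proteins, 4 were higher and 4 lower, or 4 and 6 adjusted over the list alone (camera adjusted p = 0.802, limma). Besides Rasgrp1, the GTPase-activating proteins Rasa4 and Nf1 differed by 1.68 and 0.94, and the exchange factor Rasgrp3 by 0.61. For change of these genes in either direction, fry gave an adjusted p of 3.8e-07. For such change fry passed every tested list except the mast cell and basophil and the stromal markers. Its p therefore does not set the RAS regulators apart. This list's median was 0.065 and its mean -0.089, with opposite signs, and camera's direction was upward. The median was near 0 and depended on single arrays, at -0.0081 without vector-titled array 1 and 0.015 without KRASG12D-titled array 1, and it was -0.065 without the dim 40% of genes.

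The arrays of both groups held abundant B-lineage transcripts. Pax5, the commitment factor of the lineage, was at 10.04 in both groups (difference -0.01, adjusted p = 0.966, limma). Ebf1, which acts with it, fell slightly, by 0.45 ± 0.06 from 12.19. The surrogate light-chain gene Igll1 was at 12.59 and 12.40 (difference 0.19, adjusted p = 0.0611, limma). Its partner Vpreb1 read only 4.40 and 4.28. The related Vpreb2, named after its value was seen, had a mean level of 8.37 (difference -0.21, adjusted p = 0.0503, limma). Ikzf1, which encodes Ikaros, was higher by 0.57, and Il7r, the receptor for IL-7, was lower by a log2 difference of -0.46.

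Within that background many stage-specific B-lineage genes differed. Of 27 B-lineage transcription factors, 8 were higher and 15 lower, or 8 and 16 adjusted over the list alone. The median was -0.31 (camera adjusted p = 0.0209, limma; adjusted p = 0.429 with an estimated correlation). Erg fell 9.44-fold, a difference of -3.24 ± 0.07, Ets1 fell by 1.85, and Id3, an inhibitor of E proteins, by 1.83. Spi1, which encodes the myeloid and B-cell factor PU.1, rose by 1.78 ± 0.07. Genes of V(D)J recombination were mostly lower. Rag2, a subunit of the recombinase, fell from 8.75 ± 0.16 to 5.97 ± 0.14, and Dntt, which adds untemplated nucleotides at the joints, from 7.96 ± 0.08 to 4.83 ± 0.34. The Ku subunit genes Xrcc5 and Xrcc6 fell by 1.33 and 1.15. In all 9 of 13 such genes fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 1.15e-04, limma; adjusted p = 0.0830 with an estimated correlation). Rag1 had no probe named for it alone. The myeloid-associated markers described further on rose in the same arrays, 12 of 29 of them.

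Pre-B-cell receptor signalling genes went both ways. Of 19 measured, 7 were higher and 5 lower, or 9 and 8 adjusted over the list alone (camera adjusted p = 0.745, limma). The kinase Blk fell 9.55-fold and the adaptor Lat 6.82-fold, while the adaptor Pik3ap1 rose by 1.62 and the phospholipase Plcg2 by 1.35. The median of the list was 0.12 and its mean -0.15, and camera's direction was upward. That median ran from 0.054 without vector-titled array 2 to 0.20 without vector-titled array 3. Of 14 surface markers used to stage B-cell progenitors, 5 were higher and 6 lower, also when adjusted over the list alone (camera adjusted p = 0.621, limma). Enpep, the BP-1 antigen of early pre-B cells, fell from 12.01 ± 0.02 to 8.34 ± 0.09. Ly6d fell by 2.88 and Bst1 by 1.87, and Cd22, an inhibitory coreceptor, rose by 1.63. Among 17 genes of IL-7 receptor signalling through JAK and STAT5, 6 were higher and 4 lower, or 6 and 6 adjusted over the list alone (camera adjusted p = 0.757, limma). Socs2, a feedback inhibitor of cytokine signalling, fell 4.85-fold (log2 difference -2.28, and -1.63 at a second probe), and Sh2b3, Jak1 and Stat5b rose by 1.01, 0.80 and 0.75. The median of these IL-7 genes was 0.080 and the mean -0.056, with camera upward. That median ran from 0.025 without vector-titled array 3 to 0.12 without vector-titled array 2. For change in either direction, fry gave an adjusted p of 3.4e-07 for the pre-B-cell receptor genes and also for the surface markers. It gave 5.9e-07 for the IL-7 genes. As fry passed nearly every list for such change, these values do not set these lists apart.

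**Figure D2:**
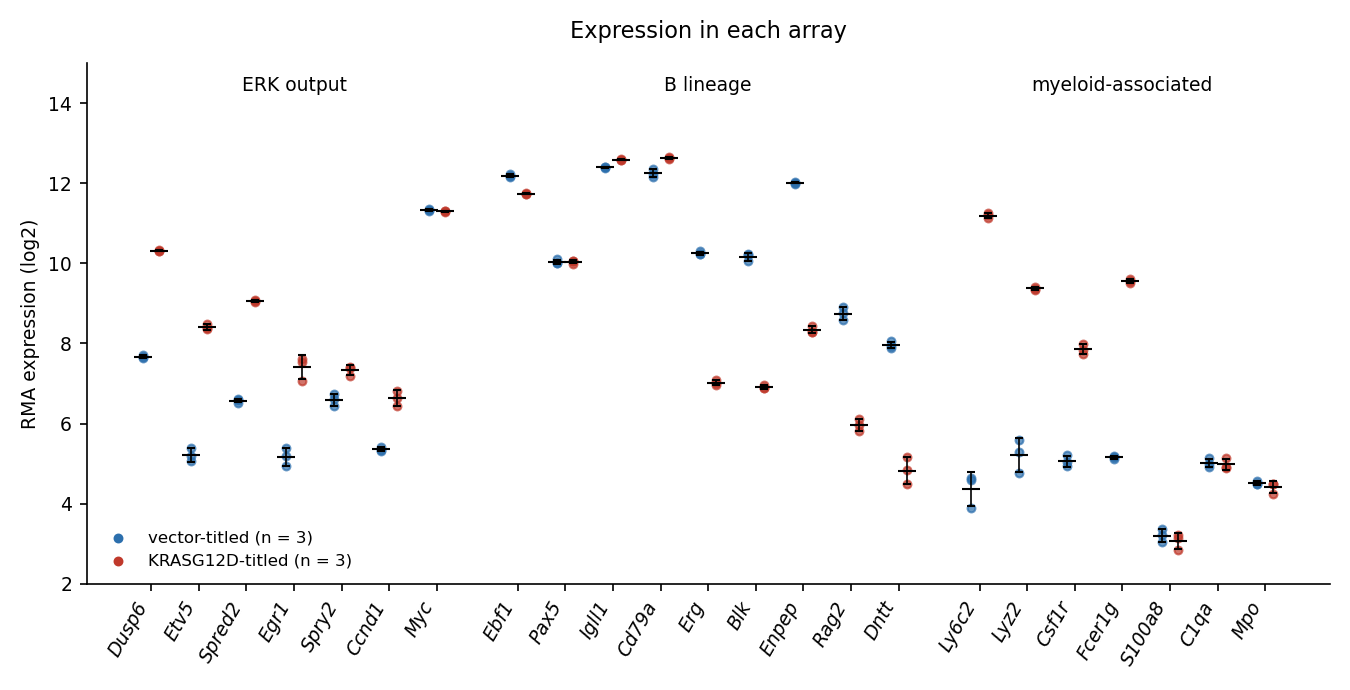
RMA expression (log2, vertical axis) of ERK output, B-lineage and myeloid-associated genes in each of the 3 vector-titled (blue) and 3 KRASG12D-titled (red) arrays, with the group mean as a bar and the SD as whiskers. Dusp6 and Etv5 are higher and Enpep, Rag2 and Dntt lower in the KRASG12D-titled arrays, while Pax5 overlaps and S100a8, C1qa and Mpo overlap at low levels. The plotted genes were chosen after their values were seen.

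Markers of other cell types were examined in the same way. Of 29 markers of monocytes, macrophages and granulocytes, 12 were higher and 1 lower in the KRASG12D-titled arrays, also when adjusted over the list alone. The camera test gave an adjusted p of 1.91e-05 (limma; adjusted p = 0.0633 with an estimated correlation). Besides Ly6c2, Fcer1g, the signalling chain of Fc receptors, rose by 4.41 ± 0.07, and Tyrobp, a similar adaptor, by 3.65 ± 0.14 from a dim 4.98. The lysozyme gene Lyz2 rose from 5.21 ± 0.42 to 9.38 ± 0.04, and Csf1r, the receptor for macrophage colony-stimulating factor, was higher by 2.80. The others that passed were Itgam (2.34), Prtn3 (2.33), Fcgr3 (2.05), Cd68 (1.85), Cd14 (1.51), Csf2ra (1.27) and Fcgr1 (0.31), with S100a9 lower (-0.31). The remaining 16 did not pass, among them S100a8, C1qa and Mpo, with differences of -0.14, -0.03 and -0.11 at mean levels of 3.13, 5.0 and 4.46. Csf1r and the genes in these last sentences were named after their values were seen. Of 21 T and NK cell markers, 3 were higher and 1 lower, also when adjusted over the list alone. These were Cd5 (2.43), Cd28 (2.11, from a dim 4.85), Klrd1 (1.68) and Zap70 (-0.78). The share of T and NK markers that passed was below the 24.9% of all tested genes. Camera gave an adjusted p of 0.745 (limma), with a median of -0.05, a mean of 0.22 and an upward direction. The T and NK median was -0.069 without vector-titled array 2, -0.0087 without vector-titled array 3 and -0.0080 after quantile normalization. Of 12 dendritic cell markers, 4 were higher and 2 lower, also when adjusted over the list alone. Among them were Cox6a2 (2.79), Cst3 (1.33, and 0.72 at a second probe), Itgax (0.79) and Cd209a (-0.57, and -0.11 at a second probe). That list had a camera adjusted p of 0.592 (limma), a median of -0.00093, a mean of 0.32 and an upward direction. That median was above 0 without vector-titled array 1 or 3 (0.017 and 0.0096) or KRASG12D-titled array 3 (0.050), after quantile normalization (0.023) or median centring (0.0061), and without the dim 40% of genes (0.22). None of 13 mast cell and basophil markers and none of 21 stromal markers passed, over all genes or adjusted over the list alone (camera adjusted p = 0.592 and 0.757, limma; fry's adjusted p for change in either direction 0.225 and 0.297). Of 11 erythroid and megakaryocyte markers 1 was lower, also when adjusted over the list alone (Car2, -1.75; camera adjusted p = 0.381, limma). Among 10 plasma cell markers 2 were higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.592, limma). Irf4 fell by 1.54, Xbp1 rose by 1.02 and Sec11c by 0.35. Jchain, at -0.34 (adjusted p = 0.0341, limma), lost its call without vector-titled array 1 or 3 (adjusted p = 0.103 and 0.0828) or KRASG12D-titled array 1 or 2 (0.112 and 0.0739).

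Inhibitory receptors, adhesion genes and genes of mature B cells were measured in the same arrays in which the myeloid-associated markers rose (12 of 29). Of 18 inhibitory receptors and phosphatases, 13 were higher and 2 lower, or 15 and 2 adjusted over the list alone. The median was 0.84 (camera adjusted p = 4.72e-08, limma; adjusted p = 0.0567 with an estimated correlation). After Lilrb4a, the largest rises were those of Btla (3.22 ± 0.16) and of Ptpn6, the phosphatase SHP-1 (2.48 ± 0.08). Inppl1, the lipid phosphatase SHIP2, fell by 2.25. Of 25 adhesion and homing genes, 11 were higher and 4 lower, or 13 and 4 adjusted over the list alone (camera adjusted p = 0.00113, limma; adjusted p = 0.124 with an estimated correlation). Ccr2, a chemokine receptor of monocytes, rose to 9.75 ± 0.04 from a dim 4.66 ± 0.35, Itgal and Itgb2, the chains of the integrin LFA-1, rose by 3.27 and 1.98, and Cxcr5 fell by 2.32. Of 23 genes of mature or antigen-presenting B cells, 10 were higher and 3 lower, or 11 and 3 adjusted over the list alone (camera adjusted p = 0.00435, limma; adjusted p = 0.225 with an estimated correlation). Cd80, a costimulatory ligand, rose by 3.00, H2-DMb2 by 2.84 and the complement receptor gene Cr2 by 2.56. The vector-titled levels of these 3 genes and of Btla were dim (4.74, 3.91, 4.74 and 4.17), so the sizes of their rises are uncertain. In the mature B-cell list 10 genes did not pass. Among them were H2-Aa (-0.01), H2-Ab1 (0.28), H2-Eb1 (-0.07) and Ciita (-0.06), named after their values were seen.

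Cytokine genes were among those that rose in the KRASG12D-titled arrays, where the myeloid-associated markers also rose. Of 26 NF-kB and cytokine genes, 7 were higher and 3 lower, also when adjusted over the list alone. Apart from Ccl3, the cytokine genes Lta and Tnf rose by 2.90 and 2.15, and Cd44, an adhesion receptor, by 1.87. The list's camera call was narrow (median 0.087, adjusted p = 0.0473, limma; adjusted p = 0.306 with an estimated correlation). It was lost without vector-titled array 2 (0.0664) or KRASG12D-titled array 2 (0.0698). It was also lost after quantile normalization (0.0591), after median centring (0.0510) and without the dim 40% of genes (0.0837). The list's median ran from 0.058 without vector-titled array 1 to 0.13 without KRASG12D-titled array 3. Of 28 interferon-stimulated genes, 3 were higher and 10 lower, or 4 and 12 adjusted over the list alone (camera adjusted p = 0.147, limma). Gbp3, Xaf1 and Iigp1 fell by 1.33, 1.00 and 0.97, and Ifih1, an RNA sensor, rose by 1.33 from a dim 4.71. Among 22 stem and early progenitor genes, 6 were higher and 2 lower, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.131, limma). Eng (endoglin) rose by 2.53, Lmo2 by 1.12 and Gfi1b by 0.96, and Mycn fell by 1.52.

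Genes of the response to amino-acid shortage and of ribosome assembly were higher or did not pass. Of 24 genes of the amino-acid response driven by ATF4, 15 rose and 0 fell (9 did not pass, limma), or 17 and 1 adjusted over the list alone. The median of this list was 0.64 (camera adjusted p = 4.72e-08, limma; adjusted p = 0.0830 with an estimated correlation). Asns, asparagine synthetase, rose 14.4-fold from 5.74 ± 0.16, Cebpb by 2.86 from a dim 4.39, Sesn2 by 1.53 and Atf3 by 1.44. Of 28 ribosome biogenesis genes linked to MYC, 16 rose and 0 fell (12 did not pass, limma), or 17 and 0 adjusted over the list alone. Camera gave an adjusted p of 1.15e-06 for them (limma; adjusted p = 0.121 with an estimated correlation), although Myc itself did not pass. The rises of Nop2, Rrp12, Nop16 and Polr1a were 0.84, 0.83, 0.82 and 0.77. Of 27 glucose uptake, glycolysis and hypoxia genes, 13 were higher and 6 lower, or 14 and 6 adjusted over the list alone (median 0.39, camera adjusted p = 0.00243, limma; adjusted p = 0.372 with an estimated correlation). Ero1a, an oxidase of the endoplasmic reticulum, rose by 1.74, the glucose transporter gene Slc2a1 by 1.54, and the glycolytic genes Pgam1 and Pfkp by 1.07 and 1.01. A second probe gave 0.13 for Slc2a1 and 0.36 for Pgam1. Of 19 cholesterol synthesis genes, 7 were higher and 3 lower, or 10 and 3 adjusted over the list alone (camera adjusted p = 0.00881, limma; adjusted p = 0.391 with an estimated correlation). The sterol sensor gene Insig1 rose by 0.90 and the synthesis genes Fdps, Lss and Ebp by 0.74, 0.72 and 0.71. The cholesterol call was also lost without the dim 40% of genes (adjusted p = 0.0559). Of 20 heat-shock and endoplasmic reticulum chaperone genes, 10 were higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 3.50e-04, limma; adjusted p = 0.0830 with an estimated correlation). The near-identical Hspa1b and Hspa1a rose by 1.75 and 0.74, and Hyou1 and Pdia6 by 0.73 and 0.67. All of these groups moved in the same arrays as the myeloid-associated markers (12 of 29 higher).

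Most genes of G2 and mitosis were lower in the KRASG12D-titled arrays. Of 29 genes of G2 and mitosis, 19 were lower and 1 higher, or 21 and 1 adjusted over the list alone. The median was -0.31 (camera adjusted p = 9.25e-08, limma; adjusted p = 0.0567 with an estimated correlation). The members had an SD of 0.248, and only Mybl2 (0.46), named after its value was seen, lay above 0. The myeloid-associated markers rose in the same arrays (12 of 29). Cenpf fell by 0.79 ± 0.08, the mitotic kinase Ttk by 0.74, Nusap1 by 0.73 and Dlgap5 by 0.58. Of 32 genes of G1/S and DNA replication, 9 were higher and 4 lower, or 14 and 4 adjusted over the list alone. Ccne1 (cyclin E1) and E2f1 rose by 0.66 and 0.63, and E2f2 fell by 0.68. The replication nuclease gene Fen1 rose by 0.59 (adjusted p = 0.0140, limma), a call lost without KRASG12D-titled array 2 (0.0523). A second Fen1 probe gave a difference of 0.31. The camera call for G1/S was borderline (median 0.11, adjusted p = 0.0486, limma; adjusted p = 0.700 with an estimated correlation). It was lost without vector-titled array 1 or 2 (0.119 and 0.0722) and without KRASG12D-titled array 1 or 2 (0.0755 and 0.108). It was also lost after quantile normalization (0.220), after median centring (0.0510) and without the dim 40% of genes (0.175). Among 14 cyclin-dependent kinase inhibitors and tumour suppressors, 5 were higher and 4 lower, also when adjusted over the list alone (camera adjusted p = 0.660, limma). Cdkn1b (p27) fell 2.84-fold and Cdkn2c 1.93-fold. Cdkn2a, the locus of p16 and p19ARF, rose by 0.68 ± 0.07. The median of the inhibitors was 0.12 and the mean -0.018, with camera upward. That median was 0.064 without vector-titled array 1, 0.16 without vector-titled array 3 and 0.059 after quantile normalization.

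Of 15 BCL2 family genes, 5 were higher and 1 lower, or 6 and 1 adjusted over the list alone (median 0.20, camera adjusted p = 0.0278, limma; adjusted p = 0.187 with an estimated correlation). Without the dim 40% of genes that call was lost (adjusted p = 0.0926). The proapoptotic genes Pmaip1 (Noxa) and Bid rose by 2.32 and 1.07. Bcl2a1a, which protects cells from death and has near-identical copies, rose by 1.04. Bcl2l11 (Bim), a promoter of cell death, fell by 0.43, a call lost without KRASG12D-titled array 2 (adjusted p = 0.0515, limma). Of 27 p53 target genes, 9 were higher and 3 lower, or 9 and 6 adjusted over the list alone (camera adjusted p = 0.0993, limma). Plk2 rose from a dim 4.19 ± 0.40 to 6.69 ± 0.41, Pltp rose 3.57-fold, and Trp53inp1 fell by 2.23. The BCL2 family genes, too, moved in the same arrays as the myeloid-associated markers (12 of 29 higher). Of the 36 lists tested, 20 passed with the preset correlation, 15 upward and 5 downward. With an estimated correlation the count was 0 in limma's camera test, with 10 lists at an unadjusted p under 0.05, and fry's directional test passed 31.

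**Figure D3:**
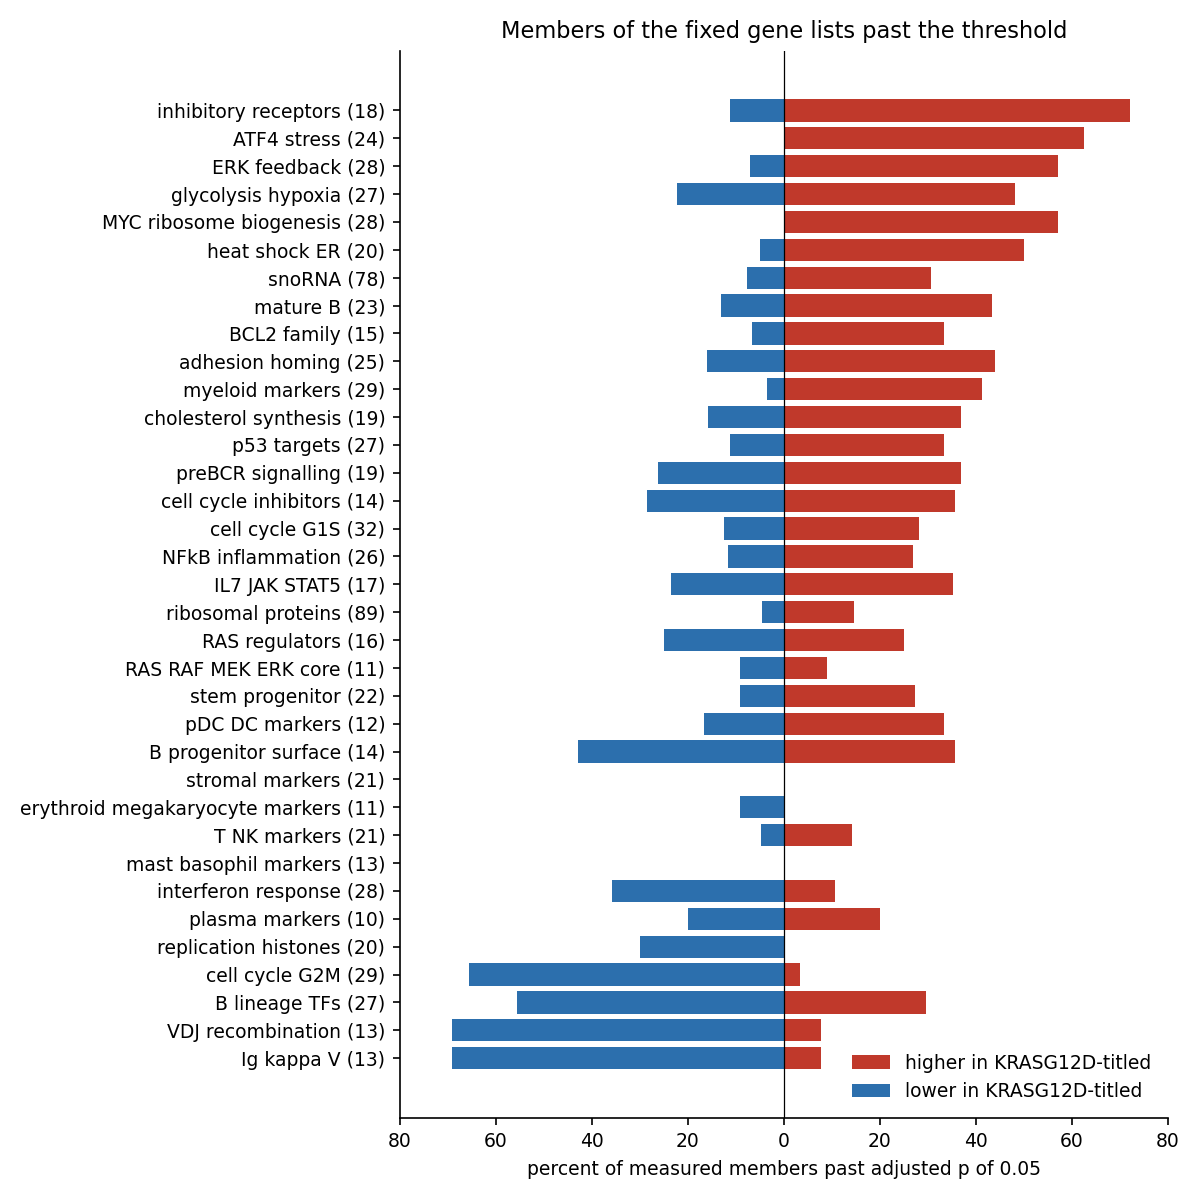
For each gene list, bars give the percent of its measured members (number in brackets) that passed an adjusted p of 0.05. Lower members lie to the left of 0 (blue) and higher members to the right (red), and lists are ordered by median log2 difference. Over all tested genes 24.9% passed, higher or lower. Inhibitory receptors stand at the top, with 13 of 18 members higher, and kappa variable segments at the bottom, with 9 of 13 lower; the microRNA list and lists with fewer than 5 measured members are not drawn.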

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

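Of the tests in this part, that of swapped titles and the count of other splits were set before the data were examined, and those on myeloid genes and on G2 and mitosis genes were chosen after the result was seen. No outlier test of single arrays was run within the groups of 3.

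Signal beyond the tested genes differed between the groups. Of the probes with no gene listed in the annotation used, 2054 passed an adjusted p of 0.05 in limma's fit of every probe, 891 higher and 1163 lower in the KRASG12D-titled arrays. Of these, 505 differed at least 2-fold, and the largest differences were 7.24 and -6.28. Of the probes assigned to several genes, 360 passed, 142 higher and 218 lower, with 58 at least 2-fold and extremes of 6.51 and -4.13.

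The direction of the comparison rests on labels that contradict each other. If the titles were swapped and the genotype field right, ERK output genes would be lower in the KRASG12D-titled arrays. Their median log2 difference was 0.519 and camera's direction was upward (unadjusted p = 8.82e-07, or p = 0.0345 with an estimated correlation), which argues against swapped titles. This rests on the assumption that activated KRAS raises ERK output in these cells, as the introduced gene had no probe of its own. For the 5512 genes past the threshold, the highest count in any other split of the 6 arrays was 0, and the real split was 1 of 10 with so many. Each other split mixes the titled groups, which puts the group difference into its spread, so a low count there was built in. A total of 10 splits is too few for a share under 0.05.

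Myeloid-associated genes such as Ly6c2, Lyz2, Fcer1g and Csf1r were far higher in the KRASG12D-titled arrays. Of the 29 list members, 3 stood above the median gene in the vector-titled arrays, 2 of them among the 12 that rose, and 0 were in another list. Granulocytes would bring S100a8, S100a9, Ngp, Ltf and Camp, whose largest difference was 0.0590 at mean levels of at most 4.71. Mature macrophages would bring C1qa, C1qb, C1qc, Adgre1 and Mrc1, whose largest difference was 0.190 at mean levels of at most 5.0. These values argue only against cells rich in those genes as the whole source. Both sets were chosen after the values were seen. Outside them the granule protease gene Prtn3 rose, while Mpo did not pass, and markers shared with monocytes rose (Cd68 1.85, Itgam 2.34). Monocyte-like cells, and granulocytic cells without the genes of the first set, stay open. Of the B-lineage genes, 6 abundant ones had a median difference of 0.0907 but went both ways (-0.45 to 0.38). Others such as Cd24a, named after its value was seen, fell (-0.92). They decide nothing on a share of monocyte-like cells. Expression of the myeloid-associated genes by the B-lineage cells themselves, the explanation that the design offers, remains a hypothesis. Bulk RNA cannot separate it from a share of monocyte-like or such granulocytic cells.

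The G2 and mitosis genes had a median difference of -0.31, with an SD of 0.248 over members and 9 of 29 not past the threshold. A scale difference left between the deposited arrays would let another scaling move their median toward 0. The higher of the medians after quantile normalization and after median centring was -0.302. RMA had already made the arrays nearly alike, so these scalings could move the median only a little. They decide nothing on a shift shared by all genes, which RMA removes. A lower share of cycling cells would also lower G1/S genes, whose median was 0.109, but the replication histones fell (median -0.24; camera adjusted p = 0.00345, limma; adjusted p = 0.257 with an estimated correlation). These values go in different directions, so a changed share of cycling cells and a changed length of the phases cannot be told apart. Whether KRASG12D has a direct part in it was not tested.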

How the results depend on the processing

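All alternatives in this part were planned before the data were examined. Without any 1 array, 4279 to 4936 genes passed, and 17 to 20 gene lists. The replicate numbers of the titles did not pair the arrays: same-numbered arrays had correlations of deviations of -0.0161, -0.0273 and -0.113, and with the replicate block 4603 genes passed, 4471 of them shared with the 5512. Over the alternatives on tested genes the count ran from 4279 to 6195. Quantile normalization gave 5459 genes, of which 48.5% were higher, against 52.9%. Among these no shared call turned its sign, except 2 genes with the mean of all probes, and the genotype field turns all of them (2595 higher, 2917 lower) by construction. The 2-fold count was 1689 with every probe in the table, which adds probes. With an estimated correlation 0 gene lists passed limma's camera test (10 at an unadjusted p under 0.05; lowest adjusted p 0.0567), where the test has only the 4 residual degrees of freedom. The highest correlation between groups was 0.926 without the dim 40% of genes and 0.969 with every probe; the cause was not tested. Of the 161 genes of the naming rule, the only ones re-run, none lost its call after quantile normalization or median centring. Among them only Jchain, H1f3, Rpl30, Rpl37, H2bc3, H2bc18, Fen1 and Bcl2l11 did so without some array, and Jchain (adjusted p = 0.0697, limma) also with the block, as did the G1/S list (0.0549). Igll1 passed without dim genes (adjusted p = 0.0229), with trend and robust settings (6.4e-05) and with array weights (0.0497, limma). Dim genes near 3 to 5 on the log2 scale carry little signal over background, so the sizes of differences that begin or end there are uncertain.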

Other observations

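The comparison of kappa segments with random lists was chosen after the result was seen.

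Immunoglobulin kappa variable segments, the gene pieces rearranged in the light-chain locus, were mostly lower in the KRASG12D-titled arrays. Of 13 measured, 9 were lower and 1 was higher, also when adjusted over the list alone (median -0.67, camera adjusted p = 9.19e-06, limma; adjusted p = 0.0633 with an estimated correlation). Igkv5-43 fell from 11.37 ± 0.10 to 9.07 ± 0.04 (log2 mean ± SD, n = 3). The differences of Igkv9-120, Igkv1-133 and Igkv9-124 were -3.27, -2.62 and -2.41, and their KRASG12D-titled levels of 2.99, 4.36 and 3.49 are near background, so these sizes are uncertain. Igkv4-91, named after its value was seen, rose by 1.82 ± 0.18 (SE). Myeloid-associated markers rose in the same arrays (12 of 29). The list's median absolute difference of 1.61 lay at percentile 100 of 10000 random lists of the same size matched on mean expression (random median 0.131, highest 0.643). Those random lists hold unrelated genes, whereas related segments can share probes and may not be independent, so the ordinary spread of genes at this level stays open. A different clonal make-up of the cultures is a hypothesis that was not tested here. None of 3 heavy-chain variable segments passed, over all genes or adjusted over the list alone, and these lists were too small for camera. The 1 lambda segment measured did not pass over all genes (difference -0.43, adjusted p = 0.0777, limma). It counted as lower over the list alone, but with 1 gene that is the unadjusted p and adds nothing.

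Small RNA genes are read here only as far as an array of long transcripts allows. Of 483 microRNA hairpins, 33 were higher and 44 lower, or 26 and 38 adjusted over the list alone (camera adjusted p = 0.359, limma). The share that passed over all genes was below the 24.9% of all tested genes. Mir3095 fell from 9.48 ± 0.23 to 4.57 ± 0.25 and Mir708 from 7.23 ± 0.15 to 3.56 ± 0.15, levels near background, so the size of these falls is uncertain. Mir3962 fell by 1.61 and Mir34b by 1.58 on the log2 scale, also to dim levels (4.46 and 4.0). Such probes can read the transcript that holds the hairpin. The list's median over all measured members was -0.040. Without the dim 40% of genes the list passed (median -0.12, adjusted p = 0.0240, limma), with a range of adjusted p over its alternatives of 0.0240 to 0.611. Of 78 small nucleolar RNAs, which guide the modification of ribosomal RNA, 24 were higher and 6 lower, or 31 and 7 adjusted over the list alone (median 0.23, camera adjusted p = 0.00113, limma; adjusted p = 0.372 with an estimated correlation). The myeloid-associated markers rose in the same arrays (12 of 29), here and for the ribosomal protein genes below. Snord52 and Snord43 rose by 1.08 and 0.83, and Snora75 and Snora62 fell by 1.38 and 0.89. Ribosomal protein genes, taken by a symbol pattern that also holds pseudogenes, gave 13 higher and 4 lower of 89, or 10 and 3 adjusted over the list alone (median 0.072, camera adjusted p = 0.0303, limma; adjusted p = 0.204 with an estimated correlation). That call was lost without vector-titled array 3 (0.0552) or KRASG12D-titled array 2 (0.0935), after quantile normalization (0.130) and without dim genes (0.0837). The share of these 89 genes that passed over all genes was also below 24.9%. Rpl17 rose by 0.71 and the pseudogene Rps15a-ps6 fell by 0.80. Rpl37 rose by 0.77, a call lost without KRASG12D-titled array 1 or 3 (adjusted p = 0.0639 and 0.0829, limma). Rpl30 rose by 0.47 (adjusted p = 0.0417, limma), a call lost without any 1 of 5 arrays, all but KRASG12D-titled array 3, with adjusted p of 0.0613 to 0.126.

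Replication-dependent histone genes, transcribed in S phase, were lower or did not pass. Of 20 measured, 6 were lower and 0 higher (limma), or 8 and 0 adjusted over the list alone (median -0.24, camera adjusted p = 0.00345, limma; adjusted p = 0.257 with an estimated correlation). In the same arrays 12 of 29 myeloid-associated markers rose. H2bc14 fell by 1.28 ± 0.09. H2bc3, H2bc18 and H1f3 fell by 0.42, 0.36 and 0.29 (adjusted p = 0.0149, 0.0182 and 0.0225, limma). Leaving out KRASG12D-titled array 1 or 3 ended the call of H2bc3 (0.0569 and 0.0539) and of H2bc18 (0.0650 and 0.0535). That of H2bc18 also ended without vector-titled array 3 (0.0576), and that of H1f3 without vector-titled array 1 (0.0690) or KRASG12D-titled array 2 (0.0830).

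Y-linked transcripts were present in both groups. The Y-linked genes Kdm5d, Eif2s3y and Uty stood at mean levels of 7.73, 9.57 and 9.11, and Xist, expressed from the inactive X of female cells, at 4.29. Of the 4 genes measured, Uty was higher by 0.30 (adjusted p = 0.0106, limma), also when adjusted over the list alone, and the others did not pass.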
